A study of Homo sapiens with 4 samples.

How the data were processed

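The measurements come from 4 G4-seq libraries of human genomic DNA, 2 with a K+ second read and 2 with a PDS second read, grouped by the labels. Per the labels, reads were 150 bp and libraries were made with an Illumina TruSeq DNA kit. The submitters' processing notes name BWA and bedtools, without versions, and the genome build hg19. Per the authors' file description, each deposited list holds the hit regions common to the 2 experiments of a condition on a strand of the alignment, and a further pair of lists holds the regions common to K+ and PDS. Per the same description, hits whose reads align to the reverse strand have their G-quadruplex on the forward strand, and the other way round, and that assignment was used here. The mismatch threshold that defined a hit and the depth required are not given in the sources used here. The lists hold only chromosome, start and end, with no score, height or count per hit, so the depth behind a hit is unknown from them. The authors' tracks of mismatch percentages and coverage were not used here.

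The contents of the lists were checked before use. Hit lengths were multiples of 15 bp in 100% of the K+ and PDS hits with guanines on the forward strand and in 99.9992% and 99.9994% of those on the reverse strand, no hits overlapped within a list, and all ends lay inside the chromosomes of GRCh37. The deposited list common to K+ and PDS was identical to the base-by-base intersection of the K+ and PDS lists in 202767 of 202767 regions on the forward strand and in 206598 of 206599 on the reverse strand. It includes 3215 and 3270 regions under 15 bp, and was not used further. Because each list is already an intersection of replicates, hits of a single library could not be compared, and differences between the conditions could not be set against the spread between libraries.

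Main values are over the autosomes, with X added as an alternative. Chromosome Y and unplaced sequence were left out, and the mitochondrial genome appears only among the additional observations. Positions are 1-based in GRCh37, with gene models from GENCODE release 44 mapped to GRCh37. A gene's TSS is the start of the gene as annotated. Overlap means at least 1 bp on the same strand. Random expectation came from circular shifts of all hits of a chromosome over its sequenced bases, 1000 for overlaps and 200 for motif classes and gene features, with 100 for alternatives, and one-sided permutation p-values in the direction of the observed difference. Intervals are 95% percentile intervals of 1000 bootstrap draws of 10-Mb blocks. Motif classes were searched on the guanine strand in this order: 4 runs of at least 3 G with loops of 1 to 7 nt, the same with at least 1 loop of 8 to 12 nt, the same with 1 bulge of 1 to 7 nt in a run, and 4 runs of at least 2 G with loops of 1 to 7 nt. Gene features were assigned by the hit's midpoint, with the promoter taken as the 1 kb upstream of the TSS. A list's share of genes with a hit within 1 kb of the TSS on either strand was compared with all other autosomal protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 16 lists and 2 conditions. It was also compared with 10000 random lists drawn to match the deciles of GC content of the window. Both comparisons treat genes as independent, although neighbouring genes can share hits, so their p-values may be too small.

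The tests, lists, named genes and alternatives were fixed before the data were examined, except where a test is said to have been chosen later. Named genes are all members of the literature list, and among autosomal protein-coding genes the 5 with the most PDS hits, and of those of at least 10 kb the 5 with the most PDS hits per kb, the 5 with the most K+ hits per kb, and the 5 with the most PDS hits per kb without a K+ hit. Not every gene that this rule gives, nor every motif of a named gene, is printed. The alternatives covered the overlap rule, strand, a minimum hit length of 100 bp, merging within 100 bp, random placement within 1-Mb windows, window and block sizes, search intervals extended by 50 bp, motif definitions, promoter windows, the choice of TSS, and X.

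The code was tested on simulated data. The motif search differed from regular expressions in 0 of 4000 intervals for each of 4 classes. Of 60 comparisons of unrelated simulated lists, 2 had a permutation p under 0.05. Among 15000 simulated genes, the exact test found 18 of 20 lists of 60 genes in which 85% of members and 60% of other genes had a hit, at p under 0.05 divided by 16. Of 300 lists with no such difference, 19 had an unadjusted p under 0.05. The Benjamini-Hochberg adjustment used for the results was not part of this simulation. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.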

Results

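Purchased human genomic DNA was sequenced by G4-seq, a polymerase stop assay for G-quadruplexes, which are 4-stranded structures of stacked guanine tetrads. Each template was read first in Na+, and then again either in K+, a cation that stabilises G-quadruplexes, or in Na+ with pyridostatin (PDS), a small molecule that binds and stabilises them. Sites where the second read departed from the first were collected as hits. There were 4 libraries, 2 in the K+ group and 2 in the PDS group, with reads of 150 bp. The deposited lists hold the regions common to the 2 experiments of a condition, separately by strand, so no spread between replicates can be computed, and the lists give no read depth behind a hit. The 95% intervals below come from resampling blocks of 10 Mb of the genome and describe variation along the genome, not between libraries. The design asks which sequences form G-quadruplexes under each stabiliser and where in the human genome they lie.

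The PDS lists held more and shorter hits than the K+ lists. The K+ lists had 525908 hits covering 136235759 bp, with a median length of 255 bp and an interquartile range of 210 to 285 bp. The PDS lists had 716311 hits covering 161821333 bp, with a median of 195 bp and an interquartile range of 165 to 255 bp. On the autosomes, to which all further values refer, there were 502299 K+ hits, or 187 per Mb (95% interval 176 to 200), and 685426 PDS hits, or 255 per Mb (238 to 275). PDS thus gave 1.36 times as many hits (95% interval 1.35 to 1.38). Hits with the guanines on the forward and on the reverse strand were about equally frequent, at 248780 and 253519 with K+ and 341251 and 344175 with PDS.

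Chromosome 19 carried the most hits per Mb under both conditions, 460 with K+ and 625 with PDS, followed by chromosome 22 with 386 and 564. Chromosome 4 carried the fewest, 124 and 159. The ratio of PDS to K+ hits was lowest on chromosome 4, at 1.29, and highest on chromosome 22, at 1.46. Across 2694 windows of 1 Mb the median was 142 K+ hits and 182 PDS hits, and the counts of the conditions had a Spearman rho of 0.985 and a Pearson r of 0.993 (rho, permutation p = 0.001, the smallest that the permutations can give), over windows that are not independent replicates. The densest window was positions 1000001 to 2000000 of chromosome 19, with 1129 K+ and 1556 PDS hits. Next by K+ hits were positions 1000001 to 2000000 of chromosome 11, with 938 and 1328, and positions 139000001 to 140000000 of chromosome 9, with 929 and 1445. The latter window lies near the end of the long arm and holds EGFL7 and AGPAT2, which are among the named genes given later.

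Most K+ hits recurred with PDS, while about as many PDS hits had no overlapping K+ hit as had one. A region called in a single library of a condition is not on its list, so absence from a list does not show absence of the structure. Of the K+ hits, 369670 (73.6%, 95% interval 72.7 to 74.5) overlapped a PDS hit on the same strand, against 6.60% ± 0.125 (SD over 1000 circular shifts) at random, a ratio of 11.2. Of the PDS hits, 360216 (52.6%, 52.2 to 52.9) overlapped a K+ hit, against 4.82% ± 0.0892, a ratio of 10.9. Both had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The ratios for K+ and PDS hits were 25.3 and 25.3 when the overlap had to span at least 50% of both hits, 21.6 and 18.4 for at least 50% of the hit itself, and 6.23 and 6.02 when strands were ignored.

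Hits with guanines on opposite strands also coincided more often than at random. With K+, 10.2% of forward-strand hits overlapped a reverse-strand hit, against 5.12% ± 0.121 over the shifts. With PDS, 51307 of 341251 did, 2.39 times the random share of 6.29% ± 0.187, and the permutation p was 0.001 for both, the smallest possible. The PDS ratio of 2.39 was 1.31 when at least 50% of both hits had to overlap and 1.58 when hits were placed at random within the same 1-Mb window.

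Guanine-run motifs were present in most hits of both lists. Each hit was assigned to the first class it held on the strand assigned to its guanines. Canonical motifs, with 4 runs of at least 3 G and loops of 1 to 7 nt, were present in 35.4% of K+ hits, against 1.63% ± 0.0337 (SD over 200 circular shifts), and in 32.0% of PDS hits, against 1.44% ± 0.0341. Motifs with a loop of 8 to 12 nt followed with 16.5% of K+ hits, 10.98 times the random share, and 18.3% of PDS hits, 13.8 times. Motifs with a bulge of 1 to 7 nt in a G run made up 22.2% of K+ hits, 5.51 times the random share, and 26.4% of PDS hits, 7.38 times. Motifs of only 2 tetrads were the first class in 12.7% of K+ and 18.3% of PDS hits, shares that the earlier classes limit. Among hits with none of the earlier classes, a comparison added after seeing the data, 2-tetrad motifs were present in 49.1% with K+ and 78.2% with PDS, against 22.7% and 20.3% at random. No motif was found in 13.2% of K+ hits and 5.08% of PDS hits, against 71.8% and 74.7% at random, ratios of 0.183 and 0.0680 that were 0.279 and 0.249 when the 2-tetrad class was left out. On the strand opposite to the assigned guanines, canonical motifs were present in 3.33% of K+ and 2.84% of PDS hits. For the canonical, long-loop, bulge and motif-free hits, each ratio to random had a one-sided permutation p of 0.005 in its direction, the smallest that 200 shifts can give. With placement within the same 1-Mb window the PDS ratio for canonical motifs was 13.9 in place of 22.2, and that for long loops 8.59 in place of 13.8.

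Hits that contained a single canonical motif extended further on its 5′ side than on its 3′ side. In 158194 such K+ hits the median distance from the motif to the hit's edge was 123 bp on the 5′ side and 109 bp on the 3′ side. In 193287 such PDS hits the medians were 109 bp and 61 bp, and the motif lay nearer the 3′ end in 74.5% of them, against 59.4% with K+.

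Hits on the PDS list alone held fewer canonical motifs than shared hits, and hits on the K+ list alone often held no motif at all. Among 325210 PDS hits without an overlapping K+ hit, 16.5% had a canonical motif, against 46.0% of the 360216 PDS hits that were also in K+, a difference of -29.5 percentage points (95% interval -29.8 to -29.2). Bulged motifs were the first class in 29.6% of the PDS-only hits and 23.5% of the shared hits, a difference of 6.09 points (5.61 to 6.59). Motifs of 2 tetrads were the first class in 29.2% and 8.34%, a difference of 20.9 points (20.5 to 21.3). These shares rise where earlier classes fall: among hits with none of the earlier classes, bulged motifs were present in 43.99% of PDS-only and 69.4% of shared hits, and 2-tetrad motifs in 77.6% and 80.3%. Among 132629 K+ hits without a PDS hit, 11.3% had a canonical motif, against 44.1% of the 369670 K+ hits also in PDS, a difference of -32.7 points (-33.2 to -32.3). No motif was found in 41.6% of the K+-only hits and in 2.96% of the shared K+ hits, a difference of 38.6 points (38.0 to 39.3). K+-only hits were shorter than shared K+ hits, with medians of 225 and 255 bp, as were PDS-only hits than shared PDS hits, with 180 and 210 bp, and a shorter hit has less room for a motif.

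**Figure D1:**
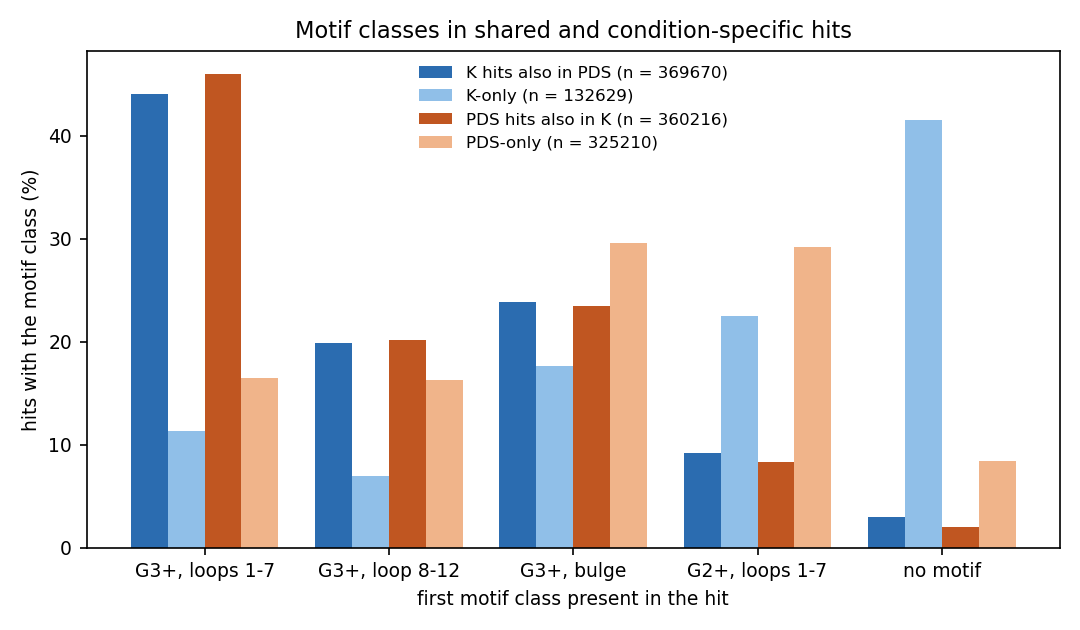
Share of hits (%, y axis) by the first motif class present (x axis), for K+ and PDS hits split by whether the other condition had an overlapping hit, autosomes. Canonical motifs fill 44.1% and 46.0% of the shared hits but 11.3% of K+-only and 16.5% of PDS-only hits, and 41.6% of K+-only hits have no motif; bars have no replicate error.

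PDS detected more of the genome's canonical motifs than K+, and the difference widened with loop length up to loop sums of 9 to 11 nt and changed little beyond them. Of 343060 canonical motifs on the autosomes, 60.4% (95% interval 59.9 to 61.0) were overlapped by a K+ hit and 74.5% (73.7 to 75.3) by a PDS hit, a difference of 14.1 points (13.5 to 14.7). Among motifs of exactly 4 G runs, those with loops summing to 6 to 8 nt were detected at 73.0% with K+ and 84.4% with PDS. The difference was 11.3 points there, 19.7 points at sums of 9 to 11 nt, 21.1 at 12 to 14 nt and 21.2 at 18 to 21 nt, where detection was 23.6% and 44.9%. Motifs with 4 or more G in every run were detected at 79.9% and 84.9%, against 54.2% and 68.5% where the shortest run had 3. Motifs with 5 or more runs were detected at 68.6% and 84.9%.

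The shortest loops were the exception to the higher PDS detection, and there a single loop order weighed heavily. Motifs with loops summing to 3 to 5 nt were detected at 75.5% with K+ and 72.1% with PDS, a difference of -3.46 points (95% interval -4.34 to -2.56). Motifs with all loops of 1 nt were detected at 63.7% and 53.8%, a difference of -9.85 points (-11.3 to -8.47). A later look at the loop bases showed that 7176 of these 14461 motifs had the loop bases T, A and A from 5′ to 3′, and these were detected at 55.5% with K+ and 28.3% with PDS. Without that loop order, in an alternative chosen after seeing the data, motifs with 1-nt loops were detected at 71.8% with K+ and 79.0% with PDS, and motifs with loops summing to 3 to 5 nt at 80.1% and 82.1%, so that PDS was higher in both. This did not hold for every kind of loop, since among motifs with 1-nt loops PDS stayed lower for T-rich loops, with a difference of -4.04 points (-6.65 to -1.39), and for mixed loops, with -5.26 points (-9.16 to -1.57). The 2910 motifs with A in all their 1-nt loops were detected at 68.2% and 88.7%, and the 1002 with T in all of them at 62.5% and 61.3%.

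**Figure D2:**
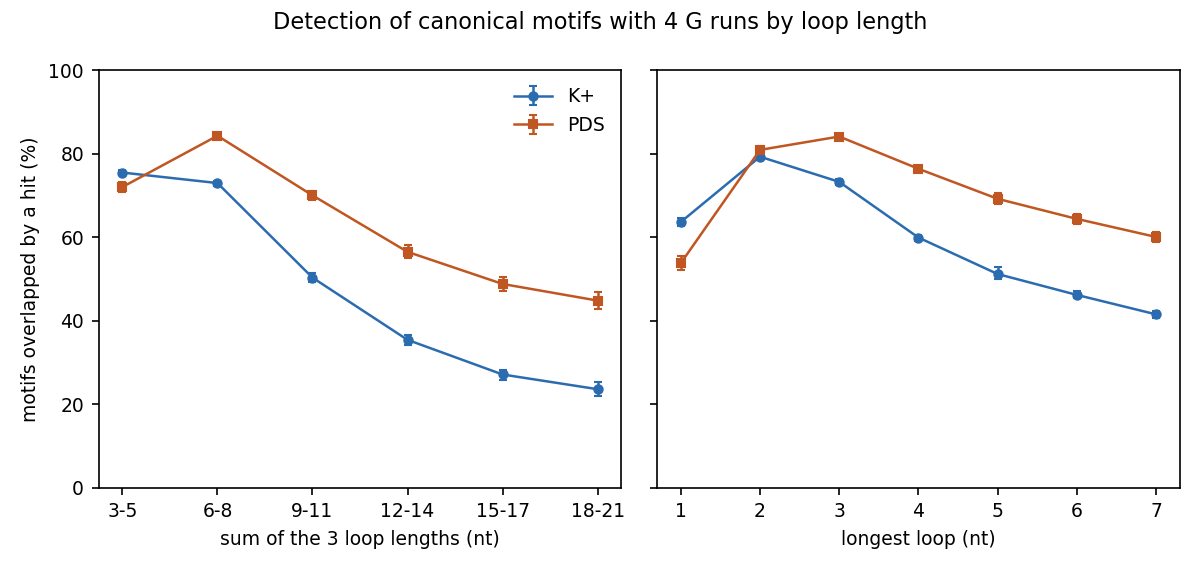
Share of canonical reference motifs with 4 G runs overlapped by a hit (%, y axis) against the sum of the loop lengths (left, nt) and the longest loop (right, nt), with K+ as circles and PDS as squares; bars are 95% bootstrap intervals over 10-Mb blocks. PDS lies above K+ except for loop sums of 3 to 5 nt (72.1% against 75.5%) and a longest loop of 1 nt (53.8% against 63.7%).

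Relative to genes, hits were most enriched in 5′ untranslated regions (UTRs) and promoters. By the position of the hit's midpoint, 5′ UTRs held 4.33 times as many K+ hits as 200 circular shifts gave and 4.87 times as many PDS hits, with 7399 and 11419 hits. The kilobase upstream of transcription start sites (TSSs) held 3.54 and 3.35 times as many, coding sequence 1.54 and 2.13 times, and 3′ UTRs 1.45 and 1.44 times. Introns held 47.5% of K+ and 46.7% of PDS hits, 1.07 and 1.05 times the random share, and intergenic sequence 44.1% and 43.9%, 0.855 and 0.854 times. Each had a one-sided permutation p of 0.005, the smallest possible. When hits were placed at random within the same 1-Mb window the introns turned to 0.986 with K+ and 0.967 with PDS, while the other features kept their direction, 5′ UTRs at 3.19 and 3.54. Counting any overlap in place of the midpoint gave 2.39 and 2.74 for coding sequence, which narrowed its contrast between the conditions.

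**Figure D3:**
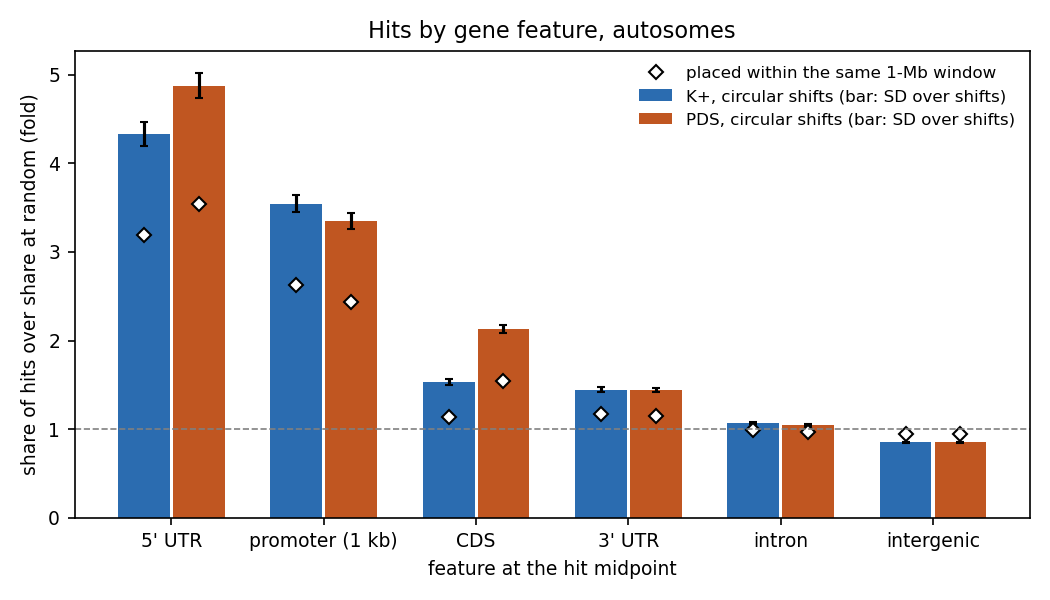
Share of hits in each gene feature over the share at random (fold, y axis) by the feature at the hit's midpoint (x axis), with K+ in blue and PDS in orange, error bars giving the SD over 200 circular shifts and diamonds the fold when hits are placed within the same 1-Mb window. The 5′ UTRs stand highest, at 4.33 with K+ and 4.87 with PDS, and introns lie at 1.07 and 1.05 with shifts but at 0.986 and 0.967 within windows.

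Canonical motifs themselves were dense in 5′ UTRs and promoters, at 796 and 714 per Mb over both strands, against 102 in intergenic sequence. The 6383 motifs in 5′ UTRs were detected at 56.0% with K+ and 82.1% with PDS, and the 5767 in coding sequence at 51.0% and 77.0%. The 144539 intergenic motifs were detected at 59.2% and 71.3%. In coding sequence, K+ hits had their guanines on the coding strand in 38.1% of cases and PDS hits in 40.7% (39.9 to 41.6), while the reference motifs there lay on the coding strand in 27.4% (25.8 to 29.0). In introns the shares were 52.8%, 53.3% and 51.3%, and in 5′ UTRs 49.4%, 50.4% and 44.8%.

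Of 19229 protein-coding genes on the autosomes, 14297 (74.4%) had a K+ hit within 1 kb of the TSS and 16051 (83.5%) had a PDS hit. Both kinds of hit were present at 13878 genes, a PDS hit alone at 2173 and a K+ hit alone at 419. Gene lists fixed in advance differed widely in this share. The HOX genes, the homeobox clusters that pattern the body axis, had a K+ hit in 38 of 39 and a PDS hit in 39 of 39 (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.000858 and 0.00423). Developmental transcription factors of the PAX, SOX, FOX and related families had a hit in 122 and 132 of 133 (exact test, adjusted p = 2.92e-06 and 1.15e-08). Potassium and calcium channel genes stood above other genes with K+, at 96 of 113 (exact test, adjusted p = 0.0209), and had a PDS hit in 97 (adjusted p = 0.724). C2H2 zinc finger genes stood above other genes with PDS, at 441 of 496 (exact test, adjusted p = 0.00194, or 0.0736 within 500 bp of the TSS), and had a K+ hit in 378 (adjusted p = 0.485). None of these calls held in the permutation matched on GC, where the adjusted p was 0.3 and 0.85 for the HOX genes, 0.63 and 0.098 for the developmental factors, 0.37 for the channels with K+ and 0.43 for the zinc fingers with PDS. Matched lists had mean shares of 88.3% and 97.0% for the HOX genes and 88.8% and 95.7% for the developmental factors, which left little room above. The HOX genes with PDS, at 39 of 39, could not have passed. Failing this permutation therefore does not show that GC accounts for the higher shares. The conditions themselves were not shown to differ for the channel or zinc finger genes, by Fisher's exact test of genes with a hit in a single condition (adjusted p = 0.746 and 1).

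Olfactory receptor, histone, keratin, and interleukin and chemokine genes had fewer hits than other genes. Olfactory receptor genes had a K+ hit in 59 of 413 (14.3%) and a PDS hit in 71 (17.2%), against 75.7% and 84.9% of other genes (exact test, adjusted p = 9.93e-148 and 1.58e-197). Replication-dependent histone genes had hits in 24 and 31 of 66 (exact test, adjusted p = 5.6e-10 and 8.88e-11). Keratins and keratin-associated proteins, the filament and matrix proteins of epithelia and hair, had hits in 64 and 100 of 149 (exact test, adjusted p = 4.67e-15 and 4.34e-06). Interleukins and chemokines had hits in 45 and 55 of 82 (exact test, adjusted p = 0.000648 and 0.000814). The size of some differences from other genes moved with the window. For histones it was -38.1 points with K+, or -18.6 within 2 kb, and -36.6 with PDS, or -57.0 within 500 bp. For interleukins and chemokines it was -19.6 with K+, or -11.8 with all transcript starts, and -16.5 with PDS, or -28.1 within 500 bp. The HOX difference with K+ was 23.1, or 15.3 within 2 kb. The other lists did not pass the test with either condition, apart from the literature genes described next. K+ and PDS hits were present at 24 and 25 of 26 other oncogenes, 15 and 20 of 22 tumour suppressors, 51 and 59 of 72 ribosomal protein genes, and 36 and 35 of 42 collagens. They were present at 27 and 30 of 35 complex I subunit genes, 36 and 46 of 56 cytochromes P450, and 10 and 11 of 11 G-quadruplex-unwinding helicases. In a permutation of list membership among genes of like GC content (10000 draws), the olfactory receptors and histones remained low with both conditions (adjusted p = 0.0016, the smallest these draws gave) and the keratins with K+ (adjusted p = 0.0077), while no other list passed. The exact tests and the draws treat genes as independent, so p-values of lists whose members lie close together may be too small.

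All 15 genes known in the literature for a G-quadruplex in or near the promoter had a hit within 1 kb of the TSS in both conditions (exact test, adjusted p = 0.0357 with K+ and 0.246 with PDS). By the same exact test the K+ call was lost when the window was widened to 2 kb (adjusted p = 0.159), when all annotated transcript starts were used (adjusted p = 0.0946), and it was absent in the permutation matched on GC (adjusted p = 0.85). MYC, the transcription factor of cell growth, had 5 K+ hits and 10 PDS hits around its TSS at position 128747680 of chromosome 8 (GRCh37). A promoter motif, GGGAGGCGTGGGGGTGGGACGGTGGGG, at 128747403 to 128747429, was detected in both conditions, while another in the promoter at 128747258 to 128747282 and a 5′ UTR motif at 128748616 to 128748638 were overlapped by PDS hits only.

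The other genes of this list differed in which condition detected their motifs. KIT, a receptor tyrosine kinase, has motifs on the coding strand at positions 55524002 to 55524021 of chromosome 4 (GGGCGGGCGCGAGGGAGGGG, intron by the annotation) and 55524052 to 55524073 (GGGAGGGCGCTGGGAGGAGGGG, 5′ UTR), and both were detected with K+ and with PDS. A promoter motif of VEGFA, the vascular growth factor, at positions 43737860 to 43737890 of chromosome 6 (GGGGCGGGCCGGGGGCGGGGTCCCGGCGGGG), was overlapped by a PDS hit only, and another at 43737542 to 43737560 by hits of both conditions. The promoter of TERT, the catalytic subunit of telomerase, holds a 68-nt motif on the template strand at positions 1295204 to 1295271 of chromosome 5, which was detected in both conditions, and TERT had 1 K+ hit and 6 PDS hits. In the promoter of INS, the insulin gene, a 237-nt stretch of G runs at positions 2182804 to 2183040 of chromosome 11 was overlapped by PDS hits only, and a 170-nt stretch at 2183051 to 2183220 by hits of both conditions, while an intronic motif at 2181968 to 2182002 was overlapped by a K+ hit only. RB1, the retinoblastoma tumour suppressor, had an intronic motif at positions 48878407 to 48878424 of chromosome 13 (GGGCGGGTGGGGCTAGGG) overlapped by a K+ hit only. Neither canonical motif near the TSS of BCL2, an inhibitor of apoptosis, was overlapped by a hit, although the gene had 1 K+ and 3 PDS hits nearby. PDGFA, a growth factor, had 8 hits in each condition and all 4 of its motifs detected. The remaining members had 2 to 7 hits per condition.

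Over whole genes, the highest PDS counts were in very long genes. PTPRN2, a receptor-type phosphatase family member of secretory vesicles, held 710 PDS and 485 K+ hits over 1049 kb of chromosome 7 (positions 157331750 to 158380515). GSE1 held 671 and 446, RBFOX1, a splicing regulator, 590 and 460, SORCS2, a sorting receptor, 565 and 380, and CAMTA1, a calmodulin-binding transcription activator, 553 and 367. Among 14335 genes of at least 10 kb the median was 0.191 K+ hits and 0.249 PDS hits per kb. The densest by PDS hits were GREP1 with 3.42 per kb, ZBTB7B, a zinc finger factor of T cell development, with 3.33, KLF16 with 3.13, EGFL7, a secreted endothelial protein, with 2.97, and CARMIL2 with 2.94. Genes dense in K+ hits included GREP1 with 2.69 per kb, SIGIRR, an inhibitory receptor of the interleukin-1 family, with 2.64, NSMF with 2.55, and ZBTB7B with 2.39. SIGIRR and NSMF had fewer PDS than K+ hits, at 26 against 31 and 24 against 30. PDS hits without a K+ hit were densest in CCDC154 with 1.47 per kb, B4GALNT4 with 1.43, TELO2 with 1.40, FBXL16 with 1.35, and AGPAT2, an acyltransferase of phospholipid synthesis, with 1.33. GSE1, SORCS2, ZBTB7B, CARMIL2, CCDC154 and TELO2 each share part of their interval with another protein-coding gene, so their hits can be counted for either.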

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

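The tests of the Alu probe, of a motif just outside the hit, of the base in the loop as a cause, of the T, A, A loop order and of the list-by-condition difference were chosen only after the results they bear on were seen. For the other tests, the deciding values were set before those values were seen, though after the patterns themselves.

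Olfactory receptor genes differed from other genes in the effect of the stabiliser. The share of genes with a hit near the TSS was 2.91 points higher with PDS than with K+ among olfactory receptors and 9.26 points higher among other genes. Of the olfactory receptor genes with a hit in only 1 condition, 35 had it with PDS and 23 with K+, against 2138 and 396 among other genes (Fisher's exact test, adjusted p = 0.000195). This was 1 of 16 lists to pass. The test was not matched on GC, and lists matched on GC to the olfactory receptors had mean shares of 27.2% with K+ and 32.4% with PDS, so part of the difference goes with low GC.

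The mitochondrial genome, which no comparison used, held 18 K+ hits and 18 PDS hits. All had their guanines on the reverse strand of the reference and 0 on the forward strand, and 16 of the K+ and 15 of the PDS hits overlapped a hit of the other condition.

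The K+-only hits without any motif numbered 55135. A motif lying just outside the hit is argued against for most of them, since with 150 bp added on both sides 12.8% gained a motif of at least 3 G per run, against 5.7% of shifted intervals that likewise held no motif, an excess of 7.08 points. Alu repeats may account for part of them: 18.1% carried the probe GTGCTGGGATTACAGG from antisense Alu sequence, against 1.36% of shifted intervals, which here could hold a motif. The complementary sequence was in 0.118%. Among K+-only hits with a motif the shares were 1.08% for the probe and 1.22% for its complement. The choice of motif-free hits left out hits with the complement that held a motif. Yet in K+-only hits with a motif the complement was also less frequent than in shifted intervals, at 1.22% against 1.48%. The same held in K+ hits also found with PDS, at 0.838% against 1.87%. These values argue against the choice of hits as the source of the strand difference of the probe. Reads were not examined, so how Alu repeats were read was not tested. Whether they are short, marginal hits stays open, because their median length was 210 bp against 240 bp in K+-only hits with a motif, a difference of -30 bp. No biological explanation was tested.

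Motifs with T-rich loops were detected more often with K+ than were motifs with A-rich loops, and the gain from K+ to PDS was 4.6 points larger for A-rich than for T-rich loops (95% interval 3.2 to 6.1). Whether the base in the loop is the cause stays open, because that value is the pattern itself and the difference did not hold at every loop length. Loop length as the sole cause is argued against, because the difference had an interval above 0 in 8 of the 10 strata of total loop length from 3 to 12 nt, while at 3 nt it was -8.43 (-11.0 to -5.71). Of the 10770 A-rich motifs at 3 nt, 7176 had the T, A, A order, detected at 55.5% with K+ and 28.3% with PDS. The strata were not computed without that order, so the reversal at 3 nt does not speak for A-rich loops in general. G-rich surroundings are argued against by a difference of 19.1 points among motifs with no GGG within 50 bp, while repeated surroundings other than the T, A, A order were not tested. Without the T, A, A loop order the difference over all motifs was 16.5 points (15.1 to 17.9), and no biological explanation was tested.

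Motifs with loops of 1 nt were detected less often than motifs with a longest loop of 2 nt, by 15.6 points with K+ and 27.1 points with PDS. Exact copies in the reference and A in the loops are argued against as the cause with K+, because the K+ gap was 14.3 points among motifs whose sequence with flanks occurs once and 15.5 points among motifs with no A in the loops. A single loop order, T, A, A, is argued against as the whole cause with K+, where 7.5 points remained without it (6.2 to 8.9) beside those 15.5. As the whole cause with PDS it is argued against too, since 2.0 points remained without it (0.8 to 3.2). The PDS gap was also 20.7 points (17.8 to 23.5) among motifs with no A in the loops, which cannot hold that order. Over all motifs, leaving out the order took the PDS gap from 27.1 to 2.0 points, so most of that gap went with the order. The gap among motifs with no A belongs to another set of motifs, and its source was not tested. Whether the order itself lowers detection was not tested either. The T, A, A motifs may be copies of LINE-1 elements that differ slightly from each other: 41.9% carried the probe AGCATTAGGAGA from the 3′ end of LINE-1 within 50 bp, against 3.01% of other 1-nt-loop motifs and 14.5% of motifs with a longest loop of 2 nt. T, A, A motifs with and without the probe were detected at similar rates, 56.9% and 54.4% with K+ and 27.0% and 29.3% with PDS. The probe was searched only as an exact match, so LINE-1 copies that differ from it count as without it. This comparison therefore cannot tell whether LINE-1 origin bears on the low detection. Neither read mapping nor a biological explanation was tested.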

How the results depend on the processing

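The alternative without the T, A, A loop order was chosen after seeing the data, and the others beforehand. A further later one, the overlap without motif-free K+-only hits, is not counted because it leaves out only hits that do not overlap. Over 73 results and 343 alternatives, 324 kept their direction and their side of the threshold, including all for the number of hits, the overlap of K+ and PDS, the strand overlap, the density along the genome and the motif classes. Introns turned from above to below random placement within 1-Mb windows, to 0.986 with K+ and 0.967 with PDS, where regional density is held fixed. Without T, A, A motifs the PDS minus K+ detection turned to 1.94 points at loop sums of 3 to 5 nt and to 7.17 points at 1-nt loops, though T-rich and mixed loops of 1 nt stayed at -4.04 and -5.26. The other changes were in gene lists, as differences in percentage points from other genes, and their cause was not tested. Calls were lost for C2H2 zinc fingers with PDS within 500 bp (3.95) and for literature genes with K+ within 2 kb (17.9) and with all transcript starts (19.98). All 15 literature genes kept a K+ hit in both of those settings, where the share among other genes was higher. Calls were gained within 2 kb for other oncogenes (17.9) and cytochromes P450 (-12.5) with K+, and with all transcript starts for potassium and calcium channels with PDS (6.93). Lists that passed in neither setting changed sign. Collagens with PDS went from -0.140 to 0.565 within 500 bp, 0.142 with hits of at least 100 bp, 2.68 with all transcript starts and 0.801 with X. Complex I with K+ went to -0.150 within 500 bp and -2.90 with all starts, and with PDS to -2.09. Ribosomal proteins with PDS went to 0.117 within 2 kb, and tumour suppressors with K+ to 1.78 with all starts. No paired analysis was possible because the lists hold only regions common to both replicates of a condition, and for the same reason no replicate could be left out. Leaving out motifs in soft-masked repeats was not run because the reference sequence used carries no soft-masking. The lists give no depth and the authors' coverage tracks were not used here, so motifs that lack a hit for want of coverage were not told apart, and the bearing of depth was not tested.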

Other observations

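The probes reported here were chosen only after the results were seen, and the comparisons with them are descriptive.

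The hits without a motif had different sequence in the 2 conditions. Among 27440 PDS-only hits without a motif, 47.1% (95% interval 45.7 to 48.4) held GAGAGAGA on the guanine strand, against 0.995% of shifted intervals, and 20.7% held GTGTGTGT, against 1.10%. Among the K+-only hits without a motif these were 0.972% and 1.65%, while 14.2% (13.8 to 14.7) held a run of 12 T, against 2.48% at random. A run of 12 A was also more frequent in them than at random, at 6.77% (6.49 to 7.04) against 2.49%. The guanine content of the K+-only hits without a motif was 22.6%, against 29.3% in the PDS-only ones and 33.1% in K+ hits also found with PDS. On the strand assigned to their guanines, these K+-only hits held more C (26.6%) and T (27.3%) than G. In the PDS-only hits without a motif and the shared K+ hits, C was below G, at 16.8% and 21.7%.

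Loop composition divided the canonical motifs of 4 runs further. Motifs with C-rich loops, in which at least 66.7% of loop bases were C, were detected at 53.8% with K+ and 76.1% with PDS, a difference of 22.3 points (95% interval 20.8 to 23.8). Most motifs, 182271, had mixed loops and were detected at 53.3% and 69.2%, a difference of 15.9 points (15.4 to 16.4). Those with T-rich loops were detected at 79.1% and 77.8%, and those with A-rich loops at 61.3% and 64.7%. The A-rich group includes the T, A, A motifs, without which it was detected at 63.6% and 78.8%, with PDS then no longer below T-rich loops. Among motifs with no GGG within 50 bp, T-rich loops were detected at 77.1% and 73.6% and A-rich loops at 52.5% and 68.0%. There C-rich loops were detected at 52.8% and 61.0%, a difference of only 8.15 points (2.53 to 13.6). The difference in these surroundings was 15.5 points for A-rich and 11.4 points for mixed loops.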
